A study of Mus musculus with 18 samples.

How the data were processed

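Genomic DNA from the tails of 9 C57BL/6 mice was measured by comparative genomic hybridisation (CGH), in which labelled DNA of a mouse and of a reference animal compete for the same probes and the ratio of their signals follows the ratio of copy numbers. The mice were a father, a mother and 7 progeny of 1 family. Per the labels, every mouse was hybridised against the same reference male in 2 dye orientations, which gave 18 arrays. The series labels give a continuous gamma-ray exposure of males at 1 mGy per day for 400 days. The title places the family under that exposure, while the design text calls the male of this family non-irradiated. That conflict was not resolved here, and no family of another exposure was analysed. Secondary screening and TaqMan assays named by the series were not analysed here.

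Arrays were scanned on an Agilent G2505C scanner and read with Feature Extraction 10.7.1.1 under the protocol CGH_107_Sep09, per the file headers. The deposited log10 ratio is that of the red (Cy5) over the green (Cy3) processed signal. The processed signal is an intensity from which Feature Extraction had subtracted background and which it had dye-normalized with a linear factor, per the file headers. A value table for all arrays, deposited by the authors, holds log2 values whose making the sources used here do not describe. Set against the scanner ratios, its columns had correlations of 0.992 to 0.999 in size and slopes of 0.983 to 0.998 in size, and the sign showed log2 of reference over mouse on every array. Its column medians lay between -0.0082 and 0.018 with 3116 missing values, and its centring stays unknown. Probe positions are on mm9, per the file headers.

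For each array, log2 ratios were taken from the processed signals, control spots and spots with an outlier flag were left out, spots of one probe were averaged, and the array was centred on the median of its autosomal probes, with no intensity-dependent correction. Ratios were then turned to log2 of mouse over reference by the dyes in the labels. The mean of the 2 orientations was 1 replicate per mouse, so that a dye effect cancels. Of 966371 spots that were not controls, 36 on unplaced chromosome pieces were left out, and 950713 placed probes remained, of which 950622 were autosomal, 68 on X and 23 on Y. The median spacing of autosomal probes was 2053 bp.

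Each mouse's autosomal ratios were cut into segments with a circular binary segmentation written in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0. It used a threshold of 7 standard errors, arcs of up to 1000 probes and removal of cuts under 5 standard errors. A lone probe more than 4 SD past its neighbours was first pulled to 2 SD from the local median. A segment counted as a region when it held at least 5 probes, its mean log2 ratio was at least 0.25 in size, and both arrays alone showed at least 0.2 in the same direction. Overlapping regions of one direction were merged across mice, and a mouse carried a merged region when its own call overlapped it or its mean over it passed the same rule. A parent carried a progeny's region when its mean was at least 0.5 of the progeny's. The same segmentation was run on the half-difference of each mouse's orientations, less its mean over the 9 mice. Copy number cancels in that track, so its calls are a guide to false calls. They had to pass the probe number and the mean size only, as the rule for both arrays cannot be applied to a single track. The segmentation was tested on simulated data by adding known changes to the half-difference track. That track stood for both arrays, so the rule that each array alone shows 0.2 was not tested, and recovery under the full rule can be lower. In the father's track, a change of 0.58 over 5 probes was recovered in 98.0% of 50 cases. In the noisier track of progeny 1 it was recovered in 48.0% of 50, and over 10 probes in 100% of 50. A change of 0.25 over 20 probes was recovered in 60.0% of 50 cases in the father's track and 42.0% in that of progeny 1.

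Shifts common to the mice and differences between progeny and parents were tested with limma 3.58.1 in R 4.3.3 on means of 47522 tiles of 20 consecutive probes, with Benjamini-Hochberg adjustment at 0.05 and, for the common shift, a size of at least 0.1. With 200 of 47522 tiles changed by 0.15 on simulated data, limma recovered 98.5% of them for progeny against parents, with 15 false calls. For the common shift it recovered 100%, with 0 false calls. Tile values had been shuffled within each mouse, so structure shared between mice, such as that of a scan batch, was absent from the simulated data. Regions of 1 parent were tested against a transmission of 0.5 with an exact two-sided binomial test. Probes on X and Y were tested with exact sign-flip and permutation tests in scipy 1.17.1. The mice are relatives, so p-values measure the spread within this family only. Per the labels the reference is 1 animal, whose own spread enters no test. The 18 arrays limit the precision.

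The scan days given by the files made 5 batches. Batch 1 held the father and the mother, batch 2 progeny 3 and 4, batch 3 progeny 1 and 2, batch 4 progeny 5 and 6, and batch 5 progeny 7. No batch held both parents and progeny. Scan day was fitted as a random block, which cannot separate the parents from their own scan batch. The consensus correlation within a scan day was -0.033 for the comparison of progeny with parents.

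Tests, thresholds, alternatives and the rule for regions named in the text were fixed before the data were examined. The rule names each region seen in a progeny and in neither parent, each region seen in all 9 mice, each region carried by a parent and not by all 9 mice, up to 10 of each, the 10 tiles with the smallest p for progeny against parents if any pass, and the fixed locus lists with up to 4 members of each that lie in a called region. Alternatives were normexp background correction of median signals with an offset of 50, loess within arrays, the deposited value table, leaving out dim probes, removal of a running median over 250 probes on either side, other minimum sizes and probe numbers, 1 orientation alone, runs of consecutive probes in place of segments, other tile sizes, scan batches and leaving out mice. Of 20 locus lists fixed beforehand, only those of the X and the Y chromosome were used. The other lists name genes, the files used here hold no gene column, and the gene table at hand is on GRCm38.p6, another build than the probes. For the same reason no gene is named, and every position is that of the files.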

Results

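The data are array CGH measurements of tail DNA from 1 mouse family, a father, a mother and 7 progeny of the C57BL/6 strain. Per the labels, each was set against 1 reference male from the same colony in both dye orientations. The series addresses whether long low-dose-rate gamma irradiation of males changes the DNA copy number of their offspring. It gives 1 mGy per day for 400 days in its title, but its design text describes the male of this family as non-irradiated. With 1 family there was no comparison between exposed and unexposed fathers. The comparisons were those within the family, where log2 ratios are of mouse over reference. One copy more than 2 would give 0.58, 2 copies more 1.0, and 1 copy fewer -1.0.

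Of the 18 arrays, 14 had a derivative log ratio spread (the noise between neighbouring probes) of 0.167 to 0.226, and the 4 arrays of progeny 1 and 2 had 0.290 to 0.299. Those 4 arrays had median green signals of 51.2 to 64.4 against 96.7 to 176 on the others, and at least 3.07% of their probes were not well above background, against 0.137% to 0.697% on the others. No probe was saturated. The noise SD of the mean of both orientations was 0.096 in progeny 7, 0.12 in the father, 0.14 in the mother and 0.18 in progeny 1 and 2. Before averaging, the orientations of a mouse correlated at -0.05 in the mother to -0.38 in progeny 7, and arrays of different mice in the same orientation correlated at 0.11 to 0.47.

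Copy number differences from the reference were few in every mouse. The segmentation called 53 regions in 9 mice, 26 gains and 27 losses, and these merged into 12 regions of the genome, 4 gains and 8 losses. The father had 9 calls, the mother 7, and progeny 1 to 7 had 4, 6, 8, 4, 5, 5 and 5. In the father, the mother and progeny 3 the chromosome 13 gain that begins at 65468928 was cut into more than 1 call. The same held in progeny 2 for the chromosome 14 loss that begins at 53414208. The number of calls thus depends in part on how a region was cut. In the half-difference track, where no copy number signal remains, the same segmentation made 5 calls over all 9 mice. There was 1 each in progeny 1, 2, 3, 5 and 6, and those of progeny 3 and 5 lay inside the chromosome 14 loss that begins at 53414208. These calls did not have to pass the rule for both arrays, and the noise of that track can differ. The 5 are therefore a guide and not the number of false calls among the 53. Of the 12 regions, 4 were carried by the father alone among the parents, 2 by the mother alone, 3 by both and 3 by neither. No region was carried by all 9 mice. The number of calls dropped to 33 with a minimum size of 0.4 and reached 96 with a minimum of 3 probes.

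**Figure D1:**
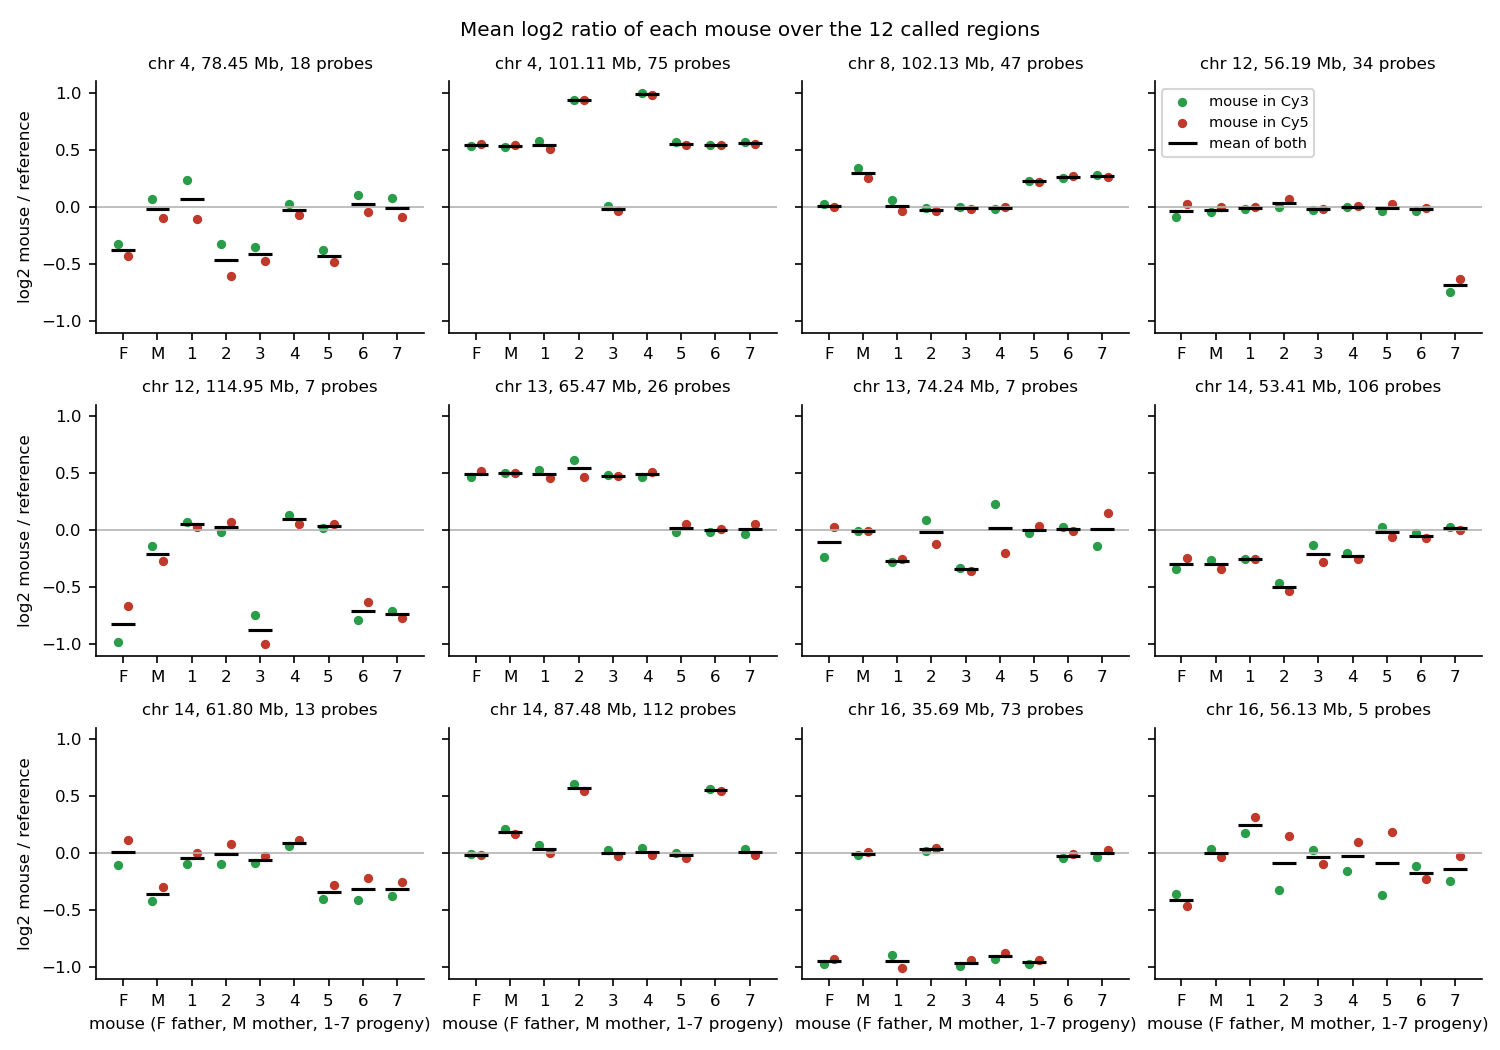
Mean log2 ratio of mouse over reference (vertical axis) of the father (F), the mother (M) and progeny 1 to 7 over each of the 12 merged regions. Green and red points are the arrays with the mouse in Cy3 and in Cy5, and black bars their mean; the longer loss on chromosome 16 separates mice between -0.96 and -0.90 from mice between -0.02 and 0.04.

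The clearest paternal change was a loss of 73 probes on chromosome 16 from 35688679 to 35848700. The father read -0.95 there and progeny 1, 3, 4 and 5 read -0.96 to -0.90, near the -1.0 of a loss of 1 of 2 copies, while the mother and progeny 2, 6 and 7 lay between -0.02 and 0.04. Under normexp background correction the father read -0.72 and progeny 1, 3, 4 and 5 read -0.43, -0.65, -0.61 and -0.76, so the nearness to -1.0 held without that correction only. A loss of 7 probes on chromosome 12 from 114953499 to 114971279 read -0.82 in the father and -0.87, -0.71 and -0.74 in progeny 3, 6 and 7. The mother read -0.20 there with an SE over probes of 0.08, and the other progeny 0.03 to 0.09. Under normexp the father read -0.42 and progeny 3, 6 and 7 read -0.38, -0.45 and -0.51. A loss of 18 probes on chromosome 4 from 78453216 to 78509511 was shallower, at -0.38 in the father and -0.47, -0.41 and -0.43 in progeny 2, 3 and 5, which is near the -0.42 of 3 copies against 4, though progeny 2 read -0.23 under normexp. A loss of 5 probes on chromosome 16 from 56134533 to 56146303 read -0.41 in the father with an SE over probes of 0.12. It was in no progeny under the main settings. Under normexp background correction that loss shrank to -0.08.

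The mother carried 2 changes that the father did not, and both were found in progeny 5, 6 and 7 and in no other progeny. A gain of 47 probes on chromosome 8 from 102125282 to 102254870 read 0.30 in the mother and 0.23, 0.26 and 0.27 in those progeny, against -0.02 to 0.01 in the other mice. A loss of 13 probes on chromosome 14 from 61798066 to 61819370 read -0.36 in the mother and -0.34, -0.31 and -0.31 in the same progeny, against -0.05 to 0.09 elsewhere. Its probes, examined after their values were seen, were not alike, as those at 61801218 and 61815353 read -1.14 to -0.60 in these 4 mice and the other 11 had means of -0.25, -0.25, -0.21 and -0.21, near or under the minimum size of 0.25. Both were smaller than a change of 1 of 2 copies. These 4 mice are also the ones with high X and low Y ratios.

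Both parents carried 3 regions. The gain of 75 probes on chromosome 4 from 101107131 to 101270535 fell into 3 levels. Both parents and progeny 1, 5, 6 and 7 read 0.53 to 0.56, progeny 2 and 4 read 0.94 and 0.99, and progeny 3 read -0.01. Among the 7 progeny, 1 had no gain, 4 the level of 1 added copy and 2 the level of 2 added copies. Under normexp progeny 2 and 4 read 0.65 and 0.84 and progeny 1 read 0.37, so the level of progeny 2 was less clear with that correction. The other 2 regions followed the scan day. A gain of 26 widely spaced probes on chromosome 13 from 65468928 to 66973977 read 0.48 to 0.54 in the parents and progeny 1 to 4, which were scanned in batches 1 to 3, and -0.002 to 0.02 in progeny 5 to 7 of batches 4 and 5. The level was not even along that gain, as the father's calls in it read 0.31, 0.87 and 0.39 and the mother's 0.30, 0.98 and 0.45. Under normexp progeny 1 and 2 read 0.29 and 0.37 over the whole gain. A loss of 106 probes on chromosome 14 from 53414208 to 54386805 read -0.29 and -0.30 in the parents, -0.50 in progeny 2 and -0.21 to -0.26 in progeny 1, 3 and 4, against -0.05 to 0.02 in progeny 5 to 7. Under normexp progeny 1 and 2 read -0.15 and -0.30 there.

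Separate signals of the channels were compared between batches 4 and 5 (3 mice) and batches 1 to 3 (6 mice) for all 12 regions, a comparison chosen after the ratios were seen. At the chromosome 13 gain the reference channel was higher by 0.50 ± 0.08 (SE) in the later batches and the mouse channel by 0.004 ± 0.08. At the chromosome 14 loss the reference channel was lower by -0.28 ± 0.08 and the mouse channel differed by 0.01 ± 0.08. The exact two-sided permutation p of the reference channel was 0.024 at both, the smallest that the 84 splits allow, and 0.071 after Benjamini-Hochberg adjustment over the 12 regions. For the mouse channel the exact p was 1.0 and 0.88. The reference channel reached the same exact p at the gains on chromosomes 4 and 8, with smaller differences of 0.03 ± 0.009 and 0.10 ± 0.04. No region passed 0.05 after adjustment in either channel. With so few splits, more regions would have had to reach the smallest p for any to pass.

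**Figure D2:**
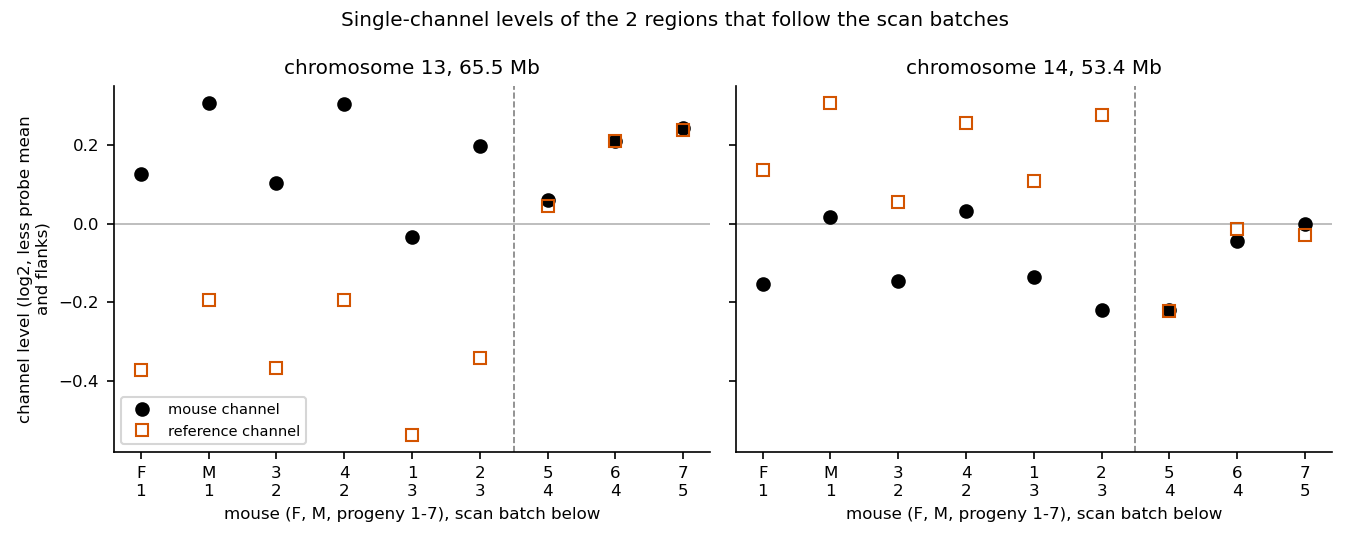
Level of the mouse channel (filled circles) and the reference channel (open squares) over the gain near 65 Mb of chromosome 13 and the loss near 53 Mb of chromosome 14, in log2 less the probe means and the flanking 250 probes on either side, for the father (F), the mother (M) and progeny 1 to 7 in order of scan batch (number below). Right of the dashed line, in batches 4 and 5, both channels of a mouse lie together; left of it the mouse channel lies 0.47 to 0.54 above the reference channel on chromosome 13 and below it on chromosome 14, by differences of -0.50 to -0.20.

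Changes seen in a progeny and in neither parent are the comparison in which an event in a parent's germ line would appear. There were 4 such calls at 3 places. Progeny 7 alone carried a loss of 34 probes (66.3 kb) on chromosome 12 from 56189969 to 56256271. It read -0.69 ± 0.03 (SE over probes), with -0.74 and -0.63 in its 2 arrays and a median over probes of -0.64. That is smaller in size than the -1.0 of a loss of 1 of 2 copies, and the reason was not tested. The other 8 mice had a mean of -0.0095 and an SD of 0.02 there (n = 8), with the father at -0.03 and the mother at -0.02. As the rank of 1 mouse among 9 by absolute size, with gains and losses counted alike, the exact p was 0.11, the smallest this design allows. The region was called from the values of progeny 7 itself, so its rank was nearly fixed beforehand and no conclusion is drawn from it. The same holds for the ranks of the other calls in neither parent. Progeny 7 was the only mouse of scan batch 5.

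A gain of 112 probes on chromosome 14 from 87480214 to 87724843 (245 kb) was called in progeny 2 and 6, at 0.58 ± 0.02 and 0.55 ± 0.01 (SE over probes), near the 0.58 of 1 added copy. Under normexp progeny 2 read 0.36 and progeny 6 read 0.53. By rank of absolute size among 9 mice the exact p was 0.11 for progeny 2 and 0.22 for progeny 6. The father read -0.01 and the other 5 progeny -0.02 to 0.04. The mother read 0.19 ± 0.01, with 0.21 and 0.17 in the 2 arrays, which is below the 0.5 share of the progeny's value that counted as carrying. With a required share of 0.25 the mother carried it. A loss of 7 probes on chromosome 13 from 74243177 to 74255486 was called in progeny 3 at -0.34 ± 0.08 (SE over probes), and progeny 1 read -0.27 without a call of its own. The father read -0.10 and the mother -0.004, and the exact p by rank of absolute size was 0.11. With a required share of 0.25 the father carried it, and 1 of the 4 calls, the loss of progeny 7, was left in neither parent. Under normexp background correction it read -0.05 in progeny 3.

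**Figure D3:**
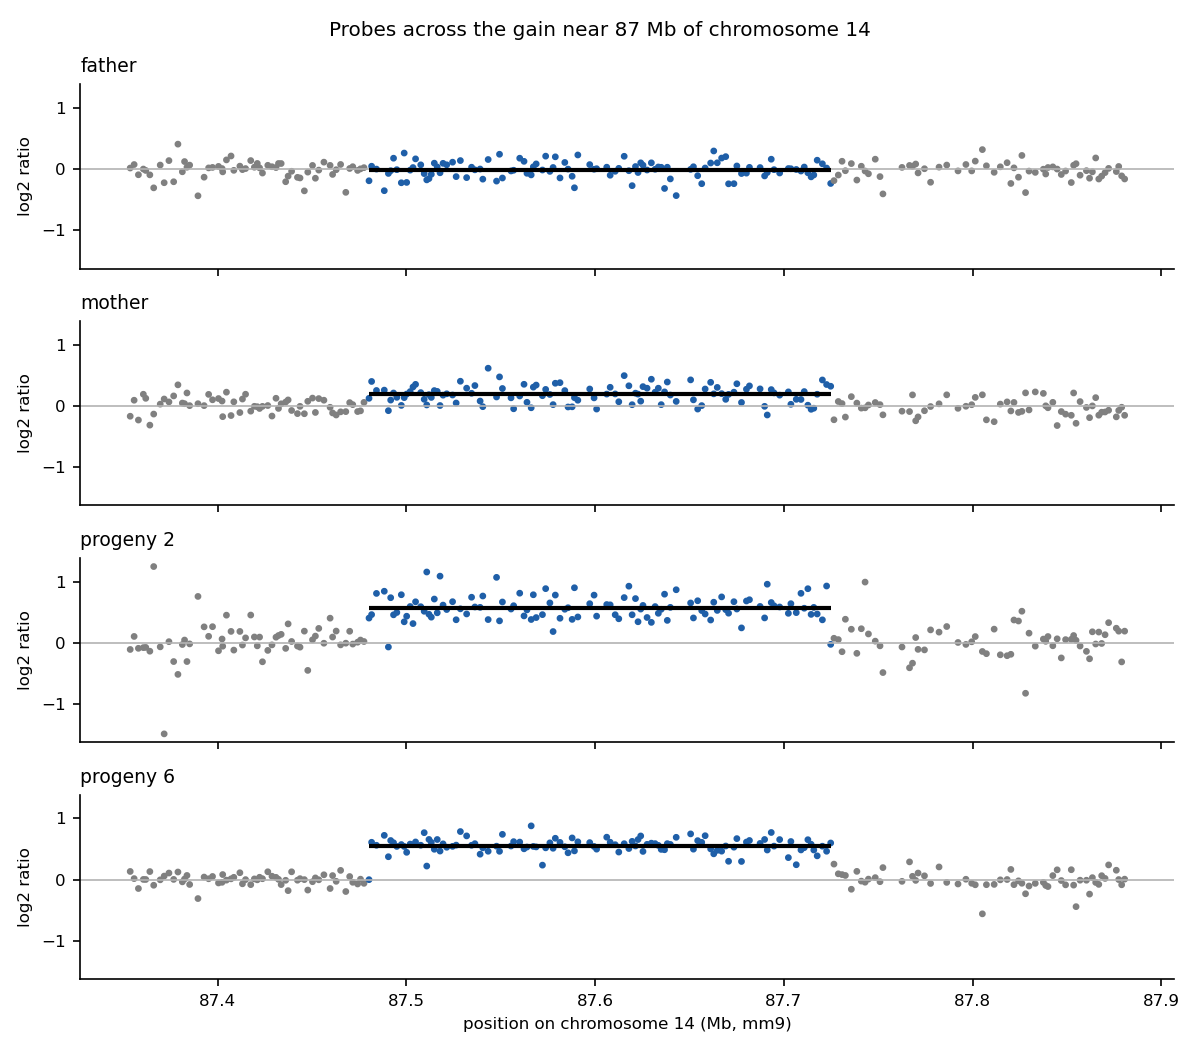
Log2 ratio of each probe (mean of both orientations) against position on chromosome 14 in Mb on mm9, in the father, the mother, progeny 2 and progeny 6. Blue points lie in the gain from 87480214 to 87724843, grey points in the 60 probes on either side, and black bars are means over the gain, at -0.01, 0.19, 0.58 and 0.55.

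Transmission of single-parent regions was tested against an even chance in the 7 progeny. Of the 6 regions tested, the longer paternal loss on chromosome 16 was in 4 of 7 progeny. The paternal losses on chromosomes 4 and 12 and the maternal changes on chromosomes 8 and 14 were each in 3 of 7. These 5 gave an exact two-sided binomial p of 1.0. Both maternal changes were in the same 3 progeny, so their tests are not independent. Those 3 are also the progeny with high X and low Y ratios. If the probes also match X or Y, the count is only that of such progeny. The tests cannot tell this from transmission of an autosomal change. The paternal loss of 5 probes on chromosome 16 was in 0 of 7, with an exact p of 0.016 and a Benjamini-Hochberg adjusted p of 0.094 over the 6 regions. With 7 progeny no smaller exact p is possible, so a single region could not pass adjustment over 6. With a minimum of 3 probes the loss held 7 probes, and progeny 7 carried it too (1 of 7, exact binomial p 0.125). With a minimum size of 0.4, 2 of 4 regions tested had an adjusted p of 0.031. They were the paternal loss of 5 probes and the maternal chromosome 14 loss. The latter was then carried by 0 of 7 progeny because their smaller values no longer counted.

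A copy number change of the reference itself would appear with the same sign in the mice that do not share it. In limma, 16 of 47522 tiles had a mean over the 9 mice that differed from 0 (6 higher, 10 lower), and 3461 had an unadjusted p under 0.05. Of the 16, 14 lay in 4 of the regions above, those of the chromosome 4 gain, at 65 Mb of chromosome 13, at 53 Mb of chromosome 14 and at 36 Mb of chromosome 16. Tile means there were 0.40 to 0.60 on chromosome 4, 0.38 on chromosome 13, -0.26 to -0.14 on chromosome 14 and -0.53 to -0.29 on chromosome 16, with limma adjusted p from 8.6e-08 on chromosome 4 to 0.015 on chromosome 16. In 4 of the 16 tiles all 9 mice had the same sign, and in 0 of them were all 9 past 0.1 in size. The count was 10 without the father and 10 without progeny 4, and 28 with tiles of 5 probes.

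The tile from 70077520 to 70134026 of chromosome 2, with a mean of 0.57 and a limma adjusted p of 0.00087, drew its shift from 4 neighbouring probes (70079530 to 70085630), too few for a region and examined after their values were seen. At these probes the father and progeny 1, 4, 5, 6 and 7 were well above background in 8 of 8 readings each, at mean log2 signals of 9.18 to 9.43. The mother and progeny 2 and 3 were well above background in 0 of 8 readings each, and the reference in 0 of 72. Against the lowest signal that counted as well above background, or the reference's own where that was higher, the father was at least 8.24-fold above the reference and progeny 1 at least 2.86-fold. The remaining tile, from 132524232 to 132567157 of chromosome 3, had a mean of -0.11 and a limma adjusted p of 0.00056, with the same sign in all 9 mice, and held a probe at 132549431 that read -3.76 in the mother and -2.55, -3.25 and -3.28 in progeny 5, 6 and 7. Without that probe the mean was -0.04, under the minimum size of 0.1.

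**Figure D4:**
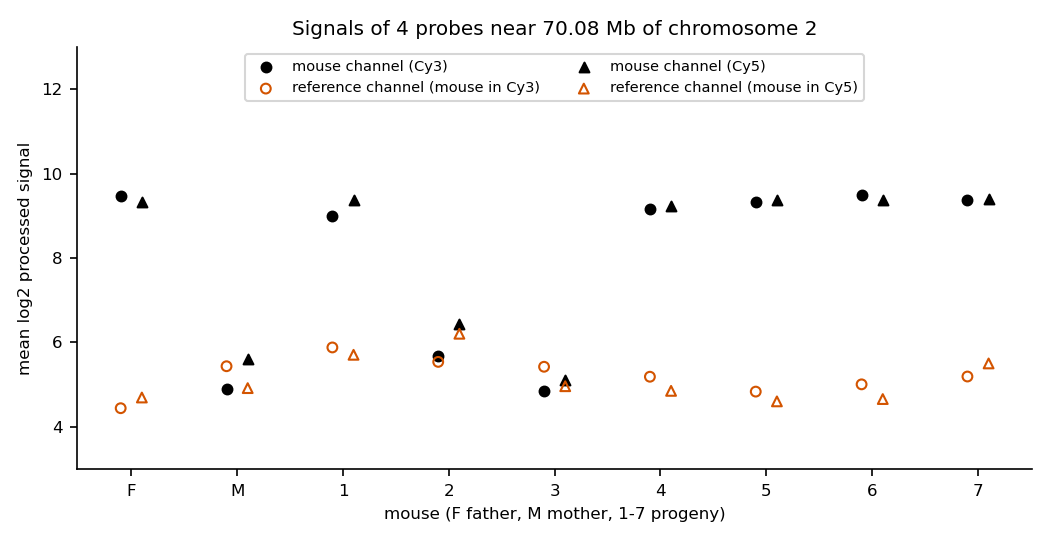
Mean log2 processed signal of the 4 probes on chromosome 2 in the mouse channel (filled) and the reference channel (open) of the father (F), the mother (M) and progeny 1 to 7, with circles for arrays with the mouse in Cy3 and triangles for Cy5. The father and progeny 1, 4, 5, 6 and 7 lie near 9, and the reference on all arrays, the mother and progeny 2 and 3 lie between 4 and 7.

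Between the 7 progeny and the 2 parents no tile differed in limma with Benjamini-Hochberg adjustment (0 of 47522), and 4632 had an unadjusted p under 0.05. With scan day as a random block the count was again 0, and 4929 had an unadjusted p under 0.05. Under normexp background correction 514 tiles passed, 312 higher and 202 lower in the progeny. The parents made up a scan batch of their own, so none of these fits can separate parents from scan day.

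Probes on X and Y showed 2 kinds of mice. The father and progeny 1 to 4 had mean ratios of -0.02 to 0.004 over 68 X probes and -0.03 to 0.05 over 23 Y probes. The mother and progeny 5, 6 and 7 had 0.93, 0.92, 0.94 and 0.94 on X and -2.31, -3.03, -2.47 and -2.35 on Y. In those 4 mice 18 to 31 of 46 readings of Y probes were not well above background, so that their Y ratios are bounds in part. The labels used here do not give the sex of the progeny. Over the 9 mice the X list had a mean of 0.41 and the Y list of -1.12, at percentiles of 100 and 0 among 10000 random probe sets of the same size. In the exact two-sided sign-flip test the p was 0.11 for both lists and 0.11 adjusted over the 2 lists, since 5 of the 9 mice lay near 0. Progeny minus parents was -0.07 on X (0.39 against 0.46) and 0.03 on Y (-1.11 against -1.14), with exact permutation p of 0.78 and 0.67, both 0.78 adjusted, where 36 splits allow no two-sided p under 0.056.

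The father and the mother were single animals and were compared by value only. The father carried 4 regions that the mother did not, all losses. The mother carried a gain and a loss that the father did not. At the 3 regions carried by both, the father's and the mother's means were 0.54 and 0.53 on chromosome 4, 0.49 and 0.50 on chromosome 13 and -0.29 and -0.30 on chromosome 14.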

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

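The tests on the scan batches' reference channel and on the mother's own channel were set before their results were seen; those on inheritance by progeny 5 to 7, on other splits of the mice, on deviating probes, on admixed DNA, on probes matching X or Y and on the size of the maternal changes were chosen only after the result was seen. Among the 7 progeny, 16 measures were searched for a value far from the rest, and chance gives about 1 in 20. Mean ratios over the 12 called regions are among these measures and were picked from the same values, so that rate does not hold for them. Progeny 7 stood apart at the chromosome 12 loss near 56 Mb with -0.69, a region called in progeny 7 alone. Progeny 1 stood apart at the paternal loss near 56 Mb of chromosome 16 with 0.25, on 5 probes. The 4 probes on chromosome 2, below the minimum for a region, read 4.82 in the father, a value that rests on a reference near background.

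The chromosome 13 gain and the chromosome 14 loss near 53 Mb separated scan batches 1 to 3 from 4 and 5. If progeny 5 to 7 had simply not inherited them, the mouse channel should differ, but it differed by 0.0035 and 0.0124, while the reference channel differed by 0.4981 and -0.2765. That argues against a lack of inheritance at chromosome 13, where the reference channel moved past 0.5 of the change in ratio by more than 2 SE, and leaves it open at chromosome 14, where the SE of 0.08 is too large. A candidate explanation for both is that the reference DNA of the later batches was not that of the earlier ones. In that channel 4 of 12 regions reached the same exact permutation p of 0.024, and none passed adjustment (0.071). As the 84 splits allow no smaller p, more regions would have had to reach it for any to pass, so the adjusted p cannot decide. Over all tiles, 4 differed between the batches, all of them in these regions, and 7 of the 84 splits of the mice gave as many. The highest other count was 10, for the mother with progeny 2 and 6. Those are the mice with raised ratios at the chromosome 14 gain from 87480214. Changes that some of the mice carry can thus add tiles to other splits, so the splits cannot decide whether chance gave the count.

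The mother's 0.19 at the chromosome 14 gain lies well below the level of progeny 2 and 6. A few deviating probes are argued against by the lowest mean of 4 equal parts of the region, 0.1765, and admixture of progeny 2 by the mother's X probes, which lie 0.1851 (SE 0.019) above the level that a share of 25.1% of progeny 2 would give. Admixture of progeny 6 stays open, since with the same share the predicted signal at the 4 chromosome 2 probes lies 0.9997 (SD 0.80) above the mother's upper bound, the predicted ratio at the 3-probe loss on chromosome 15 is -0.19 against a measured -0.01 (SE 0.05), and that at the paternal chromosome 12 loss is -0.15 against a measured -0.20 (SE 0.08), so 2 places lie against it and 1 with it. The signal is in the mouse channel, at 0.2147 above the 6 mice without the gain, against 0.03 for the reference channel. As a hypothesis, the mother may carry the gain in part of the cells, at 29.4% of the progeny's added signal. The 95% interval of 25.1% to 33.9% is over the mother's probes only. It holds the progeny's level fixed and leaves out the spread between arrays. Its lower bound is the share used for admixture above. Admixture of progeny 6 stays open, and DNA of other animals was not tested.

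The chromosome 8 gain and the chromosome 14 loss near 62 Mb were in exactly the 4 mice with high X and low Y ratios. A heterozygous change of a sequence with 2 copies is argued against by their size, since the upper bound of the gain was 0.3523 against 0.58 and the lower bound over all 13 probes of the loss -0.5233 against -1.0, although 2 of these probes alone read -1.14 to -0.60; a change at a locus with more copies, passed on by the mother, was not tested. Probes that also match X or Y are another candidate explanation. Of 11 single autosomal probes below -1.5 in both orientations in the mother and near 0 in the father, 7, 9 and 9 were as low in progeny 5, 6 and 7 and 0 in progeny 1 to 4, where 9 to 11 were measured. All 11 read -3.75 to -0.63 in progeny 5 to 7, and -0.64 to 0.15 where measured in progeny 1 to 4. The lowest share under the cut of -1.5, 63.6364%, lay between the shares set for and against a match to X or Y. That cut had also chosen the probes in the mother, so the share depends on it. With the parents exchanged, 0 autosomal probes were low in the father and near 0 in the mother. A loss of both copies in the mother would leave progeny 1 to 4 near -1.0, but their means over the 11 probes were -0.15 to -0.06. That argues against such a loss at these 11 probes. These probes lie outside both regions and were chosen as low, so they cannot show whether probes of the chromosome 8 gain match X. For the 2 regions, the explanations cannot be told apart without probe sequences set against a genome.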

How the results depend on the processing

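Leaving out progeny 1 and 2 or progeny 5 to 7, and the random block for the common shift, were chosen after seeing the data; the other alternatives were not. The 53 calls became 33 with a minimum size of 0.4, 96 with a minimum of 3 probes and 82 with runs of consecutive probes, and stayed at 38 to 57 in the other settings. The 4 calls in neither parent became 27 with a minimum of 3 probes, 17 with runs of probes, 1 with a parental share of 0.25 and 2 without progeny 5, 6 and 7, and were 3 to 5 otherwise. Transmission tests past the threshold went from 0 of 6 to 2 of 4 with a minimum size of 0.4, which left fewer regions and fewer carriers. The 16 shifted tiles became 28 with tiles of 5 probes (17 higher, 11 lower) and 5 with tiles of 100 probes. Within scan batch 4, 10 of the 16 kept direction and size. Leaving out 1 mouse gave 10 to 18 shifted tiles, with 10 each without the father and without progeny 4 (6 higher, 4 lower), and normexp gave 19 with 11 higher. Progeny against parents moved from 0 to 514 tiles under normexp and stayed at 0 in the other settings, each progeny left out included. Without the father or the mother 1 parent is left, so the spread comes from the progeny alone and no count is given for those fits. The 36 splits of the mice into 7 and 2 gave up to 321 tiles, for progeny 1 and 2. These share scan batch 3 and the lowest signal, and whether that or the mice themselves gave the count was not tested. The X mean of 0.32 under normexp and the Y median of -1.21 passed the sign-flip threshold (exact p 0.047 and 0.027). Where no reason is given, the cause was not tested.

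Of 47 means of a mouse over a region it carried, 26 moved by more than their 95% interval over probes under normexp. Its offset of 50 on both channels draws ratios toward 0, most at dim probes. Without dim probes 2 means moved, with the running median removed 2, and none under loess or the deposited value table. None changed sign. Low signal over background limits progeny 1 and 2. No paired analysis was possible because the father, the mother and the progeny are different animals of 1 family and no label pairs a progeny with a parent.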

Other observations

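The regions here were chosen after their values were seen; the test of the 4 chromosome 2 probes against background was set before its result was seen. With a minimum of 3 probes, a loss of 3 probes on chromosome 15 from 68745027 to 68748553 appeared, at -1.04 in the father and -1.05, -0.91 and -0.96 in progeny 3, 5 and 6, against -0.20 to 0.09 in the other mice. It is the size of a loss of 1 of 2 copies and was seen in 3 of 7 progeny. On chromosome 3, 3 probes from 25417435 to 25432738 read -1.59 in the mother and -1.69, -1.63 and -1.60 in progeny 5, 6 and 7, and -0.05 to 0.04 in the other mice.

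A candidate explanation for the 4 probes on chromosome 2, which span 6101 bp, is sequence missing from the reference, the mother and progeny 2 and 3. The share of reference readings well above background there was 0% (0 of 72), where a sequence present in the reference would have most of them above it. The father and 5 of 7 progeny gave signal there; the number of copies was not tested. The nearest probes that flank it end at 70077579 and begin at 70090195.

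A single probe on chromosome 13 from 95707465 to 95707524 was the only autosomal probe past 0.8 in the same direction in both orientations in all 9 mice, with means from 0.90 to 1.97.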
